A study of Homo sapiens with 17 samples.

How the data were processed

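RNA was measured in 17 libraries of K562, a human chronic myeloid leukaemia cell line that can express erythroid genes. Per the labels, cells were electroporated with CRISPR plasmids meant to activate a named gene, were then given an antisense oligonucleotide, and were processed on day 6. Total RNA was primed with oligo-dT primers carrying molecular identifiers of 12 bp and made into 3′ tag libraries, so that reads come from the ends of polyadenylated transcripts. The labels name neither the oligonucleotide nor the guide sequences.

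Each deposited file lists 228297 transcripts with estimated read counts (expected counts, which need not be whole) and TPM, in the column layout of Salmon per the file headers. The deposited TPM values were made by that quantifier from the same reads, per the file headers. The submitters' processing notes name STAR and Salmon, both as version 0.7.2, featureCounts and UMI-tools, and the builds GRCh38 and hg38. That the same version stands beside both STAR and Salmon leaves the STAR version in doubt. Whether reads with the same molecular identifier were collapsed before the deposited estimated counts were made is not given in the sources used here. The counts of low genes spread more between libraries than counting error alone gives. Repeated molecules, reassigned reads and differences between the libraries themselves cannot be told apart as the reason. Among 2524 genes averaging 1 to 2 reads in the 16 libraries other than GFP, 66.4% of the values were 0, against 24.7% for Poisson counts, with a median ratio of variance to mean of 5.98. Poisson intervals and floors of 3 reads therefore cover counting error only and are too narrow.

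Estimated counts were summed per gene with GENCODE 29 (GRCh38), matching transcripts by identifier without its version. Of the transcripts, 205336 matched, and they held 96.4% to 96.7% of the reads. The remaining transcripts, with 3.32% to 3.6% of the reads, have no gene in the annotation used and stayed out of library sizes and tests, except in 1 alternative that kept them. Gene sums were rounded to whole numbers for tests. CPM (counts scaled to the reads in genes) were computed here from the deposited estimated counts. The protocol's strand setting is not given in the sources used here, so overlapping genes on opposite strands are uncertain, as are near-identical copies, between which the quantifier divides reads.

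Groups followed the plasmid label. The labels GOLGA8N and LAPTM4B each had libraries titled 1 and 2, and 13 other labels had 1 library each. A label with a number before the gene (20-, 21-, 22-, 23-) was pooled with the unprefixed label of the same gene. The GOLGA8N arm was GOLGA8N 1, GOLGA8N 2 and 23-GOLGA8N, the LAPTM4B arm LAPTM4B 1, LAPTM4B 2 and 22-LAPTM4B, and the reference arm Neg, GFP and RFP, whose labels name no human gene. The labels do not say what the prefixes, the numbers 1 and 2, Neg or E7 stand for, nor that libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

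Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, robust quasi-likelihood fit and test) on the 9 libraries of the 3 arms in 1 fit, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Gene lists were fixed before the data were examined, and the 37 with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. The targeted genes were compared by permuting the library labels (100000 draws, one-sided), and for each gene by an exact one-sided permutation test. The transcript of 1 gene was aligned to the GENCODE transcripts with blastn 2.17.0. Alternatives were DESeq2 1.42.0, limma-voom, other size factors, other filters, other sets of reference libraries, unprefixed labels only, a summed GOLGA8 family and leaving out each library in turn.

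The genes named were set by a rule fixed before the data were examined. It took the targeted genes and tested GOLGA8 members; where fewer than 10 genes passed, the 10 with the lowest p; and up to 4 members with the lowest p of each called list and of the Golgi, endosome, lysosome, endocytosis, oligonucleotide-binding and interferon lists. For a single library it took the 3 genes with the largest log2 ratio, at a pseudocount of 1 CPM, to the median of the libraries not named for the same gene, among genes at 10 CPM or more. It also took genes within 100 kb of a target.

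The fit was tested on simulated counts with 200 changed genes drawn for GOLGA8N against reference, where 11119 genes were tested. It recovered 39 of 50 genes changed 8-fold, 19 of 50 changed 4-fold, 4 of 50 changed 2-fold and 1 of 50 changed 1.5-fold, with 5 false calls among 68. In a separate draw, a lysosome list raised 1.5-fold was called by camera with both correlations, at adjusted p of 1.41e-16 and 0.00252. Genes were drawn independently of one another there. In the data the estimated correlation of the ribosomal protein list was 0.212, for GOLGA8N against reference. The draw therefore does not show whether the estimated correlation lets such a list be called.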

Results

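The data were 3′ tag RNA profiles of K562 cells carrying plasmids for CRISPR activation of single genes and treated with an antisense oligonucleotide. The series title links GOLGA8 genes, which encode golgin proteins of the Golgi apparatus, to uptake and activity of such oligonucleotides. There were 17 libraries under 15 labels, of which 13 libraries named 1 of 9 human genes. Library totals ran from 569057 estimated reads in GFP, through 2252097 in 23-GOLGA8N, the next lowest, to 4236396 in 20-ARSF, with a median of 3222049. At 3 reads the floor was 5.46 CPM in GFP and 0.733 CPM in 20-ARSF. GFP stood apart: its Spearman correlation with each other library was 0.761 to 0.79, against 0.842 to 0.911 among the other libraries, across 8473 genes, which are not independent replicates. No pair of libraries agreed within counting noise; the lowest chi-square per degree of freedom among 136 pairs was 7.62, for 22-LAPTM4B and 23-GOLGA8N.

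The first question was whether each targeted gene was highest where it was named. TTR, the thyroid hormone carrier transthyretin, had 40 estimated reads (11.7 CPM) in its own library and 5 in the 16 others together, where its highest level was 1.15 CPM. UBE2V1, a ubiquitin-conjugating enzyme variant, was at 129 CPM in its own library, against 90.6 ± 16.9 (SD, n = 16) and at most 124 CPM in the others. CTPS2, a CTP synthase, was at 16 CPM in its own library, below the highest other library at 18.3 CPM. LAPTM4B, a lysosomal membrane protein, was at 189 ± 29.7 CPM (SD, n = 3) in its own libraries and 227 ± 43.3 (SD, n = 14) in the others. ADORA2A had 0 reads in its own library and 41.4 over 7 others, up to 3.24 CPM in E7. COL6A6 had 0 reads in its own library, and ARSF and TRPC5OS had 0 reads in every library.

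GOLGA8N (ENSG00000232653, GRCh38 chromosome 15, 32593456 to 32607310, plus strand) received 0.7 estimated reads in its 3 libraries together and 1.3 in the 14 others. The named gene was higher than in every library not named for it in 3 of 13 libraries, TTR, UBE2V1 and 23-GOLGA8N, the last on 0.7 reads (permutation p = 0.0358, one-sided, with a mean of 0.7 libraries by chance). The count fell to 2 with deposited TPM (permutation p = 0.152) and with the GOLGA8 family summed (permutation p = 0.158). For single genes the smallest exact permutation p was 0.0588, reached by TTR and UBE2V1 and the lowest that 1 library among 17 allows; adjusted over 9 genes it was 0.265.

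The GOLGA8 family sum over 21 annotated members was 74.4 ± 6.84 CPM (SD, n = 3) in the GOLGA8N libraries and 69.6 ± 21.8 (SD, n = 14) in the others (exact one-sided permutation p = 0.351). GOLGA8A and GOLGA8B supplied 95.2% of it. A feature outside the family by name behaved differently. AC091057.3 (ENSG00000269930), a lincRNA on chromosome 15 from 30616958 to 30617749 on the plus strand, lies 2397 bp beyond GOLGA8H. It had 76.3, 50.1 and 17.1 CPM in GOLGA8N 1, GOLGA8N 2 and 23-GOLGA8N, and at most 2.01 CPM in the 14 others, with 370.5 reads against 22.3. Its 792-nt transcript aligned at 97.6% identity over 794 positions to GOLGA8N, within the 3′ UTR in exon 19 (32606373 to 32607159), and at 90.5% or less to GOLGA8EP, GOLGA8CP, GOLGA8G and GOLGA8F over a similar length. Reads of these copies can be exchanged by the quantifier, so the locus of origin is uncertain.

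**Figure D1:**
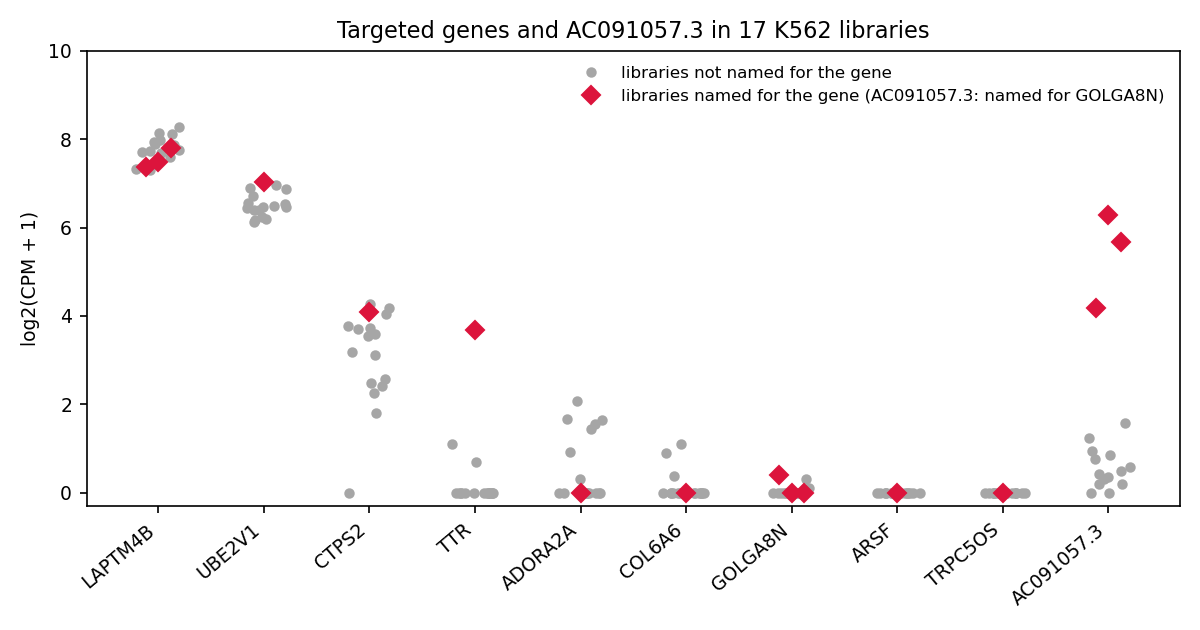
Each point is 1 library, on a log2(CPM + 1) axis; diamonds are libraries named for the gene, and for AC091057.3 those named for GOLGA8N. AC091057.3 was at 17.1 CPM or more in the GOLGA8N libraries and at most 2.01 CPM elsewhere, whereas the LAPTM4B diamonds lie among the other libraries.

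The GOLGA8N arm was compared with the reference arm to find genes that changed with the plasmids. Of 11916 genes tested by edgeR, 2 were called, both higher in the GOLGA8N arm. AC091057.3 rose by 6.44 ± 0.885 on the log2 scale (SE, 3 against 3 libraries; edgeR adjusted p = 0.00529), a size that rests on 4 reads in Neg; without Neg it was 10.04 ± 1.43 (edgeR adjusted p = 0.0116). TIMP1, a secreted inhibitor of matrix metalloproteinases, rose by 1.19 ± 0.197 (SE; edgeR adjusted p = 0.0386), and its CPM did not overlap between the arms. There were 675 genes at an unadjusted p under 0.05, against 596 by chance, and 11.8% of the genes had arms that did not overlap, where chance gives 10%. DESeq2, given 24447 genes with no filter on low counts, called 14, and limma-voom called 4 of the same 11916.

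The other 8 of the 10 genes with the lowest p missed the threshold in edgeR. PAEP, the lipocalin glycodelin, was at log2 2.78 ± 0.556 (SE), and TAGLN2, an actin-binding protein, at 0.59 ± 0.133. The mitochondrial transcripts MT-TN, MT-ND5, MT-TA and MT-ND1 were at log2 0.86, 0.61, 0.62 and 0.47. FERMT2 had 0 reads in the GOLGA8N arm and 90, 32 and 0 in Neg, RFP and GFP, while RPL23AP42, a ribosomal protein pseudogene, had 54, 3 and 20 reads in GOLGA8N 1, GOLGA8N 2 and 23-GOLGA8N and 0 in the reference arm. LAPTM4B was at -0.09 ± 0.205, GOLGA8A at -0.02 ± 0.363 and GOLGA8B at -0.64 ± 0.365, none called. With the label prefix as a term, a fit chosen after the data were seen, edgeR called 6 genes. These were AC091057.3, TIMP1, PAEP at log2 3.11 (edgeR adjusted p = 0.0111), STC1, a secreted glycoprotein hormone, at 5.25 (edgeR adjusted p = 0.0111), MT-TQ at 0.96 and the lower UPK3BL1. STC1 was also called by DESeq2, at log2 5.19.

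The 2 calls differed in where they held. TIMP1 was also called by DESeq2 (log2 1.15, DESeq2 adjusted p = 0.000137) and by limma-voom (log2 1.13, limma-voom adjusted p = 0.0321). With unprefixed labels only, edgeR called it at log2 1.40 (edgeR adjusted p = 7.64e-05). AC091057.3 was called by DESeq2 and with unprefixed labels only as well. TIMP1 lost its call without each of 5 libraries in turn: Neg, GFP, RFP, GOLGA8N 1 and GOLGA8N 2, with edgeR adjusted p of 0.07, 0.205, 0.238, 0.115 and 0.0957. Its log2 fold there was 1.27, 1.14, 1.17, 1.09 and 1.05, close to the 1.19 of all 9 libraries. It also lost the call with all 17 libraries in the fit (log2 1.18, edgeR adjusted p = 0.562), with the stricter filter (1.18, 0.0656) and with unmatched transcripts kept (1.18, 0.0572). AC091057.3 lost its call without GOLGA8N 1 (log2 5.96, edgeR adjusted p = 0.0983) and with limma-voom (log2 6.34, limma-voom adjusted p = 0.413), against log2 6.44 in the edgeR fit of 9 libraries. The label prefix separated TIMP1 further. GOLGA8N 1 and 2 were at 892 ± 34.8 CPM (SD, n = 2), against 334 ± 63 (SD, n = 11) and at most 426 CPM in the other unprefixed libraries. 23-GOLGA8N was at 524 CPM, inside the 440 to 601 CPM of the other 3 prefixed libraries. PAEP was at 64.8 ± 16.4 CPM (SD, n = 2), against 7.48 ± 4.33 (SD, n = 11), and at 22.1 CPM in 23-GOLGA8N, above the 4.34 to 19.2 CPM of the other 3 prefixed libraries. Against all 14 libraries not named for GOLGA8N, edgeR called 4 genes: AC091057.3 at log2 6.58 ± 0.533 (SE), PAEP at 2.59, TIMP1 at 1.09 and the lower AC068768.1 at -1.61. AC091057.3 was higher on both sides of the prefix, at 17.1 CPM in 23-GOLGA8N against at most 0.81 in the other 3 prefixed libraries.

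**Figure D2:**
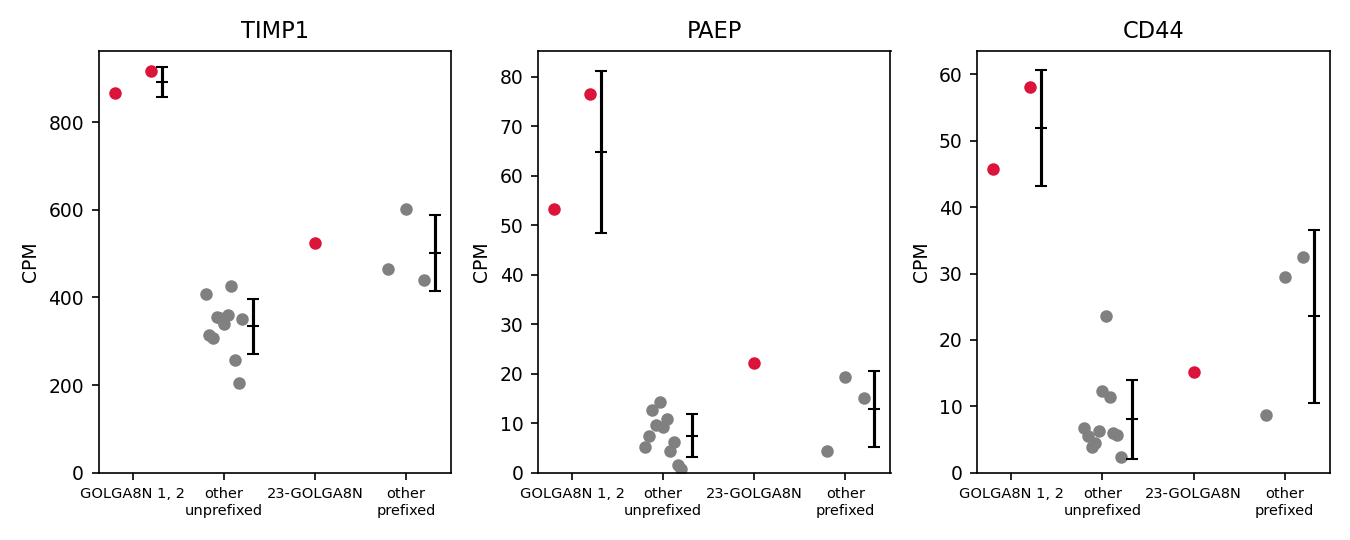
CPM of TIMP1, PAEP and CD44 per library (points), with mean and SD beside groups of more than 1, split by label prefix. GOLGA8N 1 and 2 lie above all other unprefixed libraries, while the TIMP1 point of 23-GOLGA8N (524 CPM) lies within the other prefixed libraries.

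Among the gene lists, 4 were called higher in the GOLGA8N arm than in the reference arm by camera with the preset correlation. Of 78 cytosolic ribosomal protein genes, 72 were higher, with a median log2 of 0.2 (camera adjusted p = 6.62e-08), RPL27A at 0.49, RPS27A at 0.48, RPS4X at 0.42 and RPS20 at 0.41 among them. Of 36 erythroid genes, 28 were higher (camera adjusted p = 0.000428), with the globins HBE1 at 0.70, HBZ at 0.58 and HBD at 1.70. Of 13 mitochondrially encoded genes, 12 were higher (camera adjusted p = 0.00234), as were 56 of 73 nuclear genes of oxidative phosphorylation (camera adjusted p = 0.00587), among them COX7A2 at 0.56, ATP5MG at 0.55 and UQCRB at 0.48. No member passed over all genes; adjusted over the list alone, 6, 0, 5 and 4 members passed. With an estimated correlation none of the 4 lists was called, at adjusted p = 0.955, 0.375, 0.955 and 0.975, nor by fry, whose lowest adjusted p among the 4 was 0.104. Reads in ribosomal protein genes were 22.5% ± 0.76 (SD, n = 3) in the reference libraries and 24% ± 0.57 (SD, n = 14) in all others (exact two-sided permutation p = 0.0015). The mitochondrial share, at 14.5% ± 0.75 (SD, n = 3) and 15.6% ± 1.22 (SD, n = 14), did not pass the threshold (exact two-sided permutation p = 0.156). Neither test of shares was planned, and the ribosomal one reuses the genes and reference libraries of the list call. The 4 prefixed libraries, none in the reference arm, held the highest ribosomal shares, from 24.28% in 20-ARSF to 24.95% in 22-LAPTM4B. The highest unprefixed share was 24.15%, in E7.

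**Figure D3:**
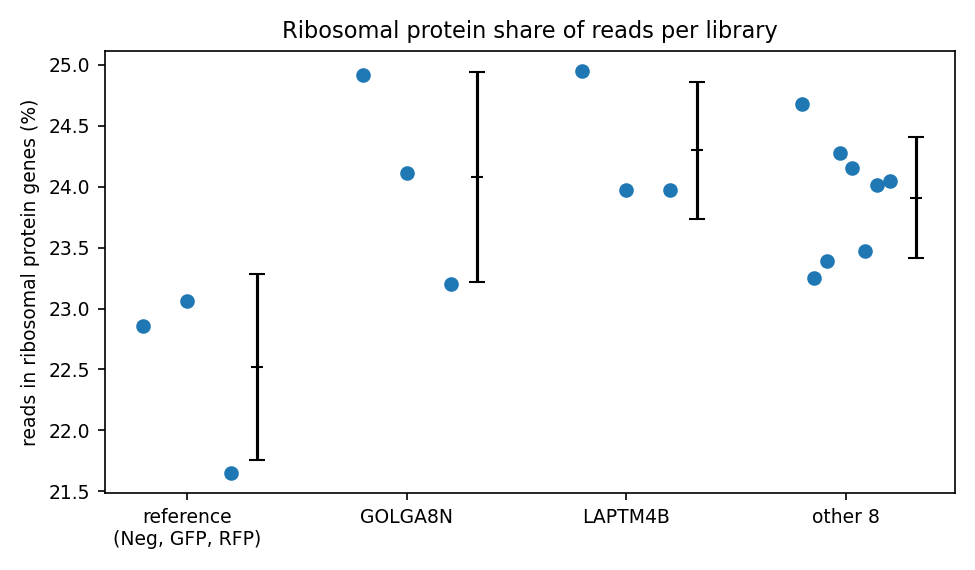
Percent of reads in ribosomal protein genes per library (points), with mean and SD beside each set, on an axis that does not start at 0. The 3 reference libraries average 22.5%, and no other library is below 23.2%.

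The lists nearest to the series title were not called. For the lysosome, 37 of 57 genes were higher (camera adjusted p = 0.195), with CTSL at log2 0.56 ± 0.27 and TFE3 at 0.88 ± 0.394 (SE). The other golgins were higher for 15 of 22 (camera adjusted p = 0.438), with GOLGA3 at 0.70 ± 0.38. Genes of ER-Golgi vesicle coats were higher for 23 of 40 (camera adjusted p = 0.686), with COPG2 at 0.73 ± 0.218, and those of Golgi-endosome retrieval for 14 of 29 (camera adjusted p = 0.737), with SNX1 at 0.77 ± 0.294 and AP1B1 at -0.48 ± 0.242. Endosome and ESCRT genes were higher for 21 of 43 (camera adjusted p = 0.974), with CHMP1A at -0.81 ± 0.355, ANXA2 at 0.47 ± 0.206 and RAB11A at -0.38 ± 0.199. Endocytosis genes were higher for 14 of 31 (camera adjusted p = 0.946), with FLOT2 at 0.56 ± 0.214, EPN1 at -0.43 ± 0.209 and EPN2 at -1.10 ± 0.614. Proteins known to bind phosphorothioate oligonucleotides were higher for 23 of 35 (camera adjusted p = 0.686), with XRCC6 at 0.48 ± 0.191, TCP1 at -0.40 ± 0.165 and NPM1 at 0.27 ± 0.117. Interferon response genes were higher for 10 of 15 (camera adjusted p = 0.946), with IRF1 at -0.73 ± 0.479. None of the members named here passed over all genes.

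The LAPTM4B arm showed no called gene against the reference arm in edgeR, among 11916 tested. There were 469 at an unadjusted p under 0.05, fewer than the 596 by chance. DESeq2, given 24447 genes with no filter on low counts, called 1 gene. limma-voom called 2, MT-ND5 and MT-RNR1 (limma-voom adjusted p = 0.0262 and 0.045). LAPTM4B itself was at log2 -0.29 ± 0.204 (SE, 3 against 3 libraries; edgeR adjusted p = 0.999), with 189 CPM in its own libraries. Its arms did not overlap, which held for 10.1% of all genes tested, where chance gives 10%. The lowest p values in edgeR belonged to MT-ND5 at 0.65 ± 0.135 and MT-TN at 0.70 ± 0.16, followed by RPS27A, MT-RNR1 and OST4 at 0.53, 0.43 and 0.75. None of these passed the threshold in edgeR. Cytosolic ribosomal proteins were higher for 74 of 78 genes (camera adjusted p = 1.09e-09), oxidative phosphorylation for 60 of 73 (camera adjusted p = 0.00256), the erythroid list for 27 of 36 (camera adjusted p = 0.00868) and the mitochondrially encoded list for 9 of 13 (camera adjusted p = 0.0347). With an estimated correlation none was called, at adjusted p = 0.82, 0.82, 0.82 and 0.868. The lysosome list, to which LAPTM4B's protein belongs by location, was higher for 39 of 57 (camera adjusted p = 0.208), with LAPTM4A at 0.43 ± 0.207. Both arms were set against the same 3 libraries. Their fold changes correlated across 11916 genes with r = 0.696, where unchanged simulated arms gave a mean of 0.545. The covariance was 0.421 against 0.264. The simulation drew all libraries from a common profile with independent genes, so it lacks the departure of GFP and any structure by prefix. The excess over it therefore does not show a shared effect of the plasmids.

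Set directly against the LAPTM4B arm, the GOLGA8N arm differed in 1 gene. AC091057.3 was higher by log2 7.68 ± 0.921 (SE, 3 against 3 libraries; edgeR adjusted p = 0.000657). TIMP1, at 1.00 ± 0.195, PAEP, at 2.46 ± 0.52, and CD44, a hyaluronan receptor, at 2.14 ± 0.579, missed the threshold, as did SNRPFP1, AC068768.1 and NEU3 at 1.99, -1.80 and 1.37. There were 243 genes at an unadjusted p under 0.05, fewer than the 596 by chance. None of 37 lists was called; ribosomal proteins were higher for 35 of 78 (camera adjusted p = 0.927) and the lysosome list for 29 of 57 (camera adjusted p = 0.927). DESeq2, given 24447 genes with no filter on low counts, called 2 genes, TIMP1 among them (log2 1.01, DESeq2 adjusted p = 0.00949), and limma-voom called 0. edgeR called TIMP1 with unprefixed labels only (log2 1.40, adjusted p = 0.000404), without 22-LAPTM4B (1.18, 0.0474), without 23-GOLGA8N (1.22, 0.00394), with no filter (0.98, 0.000224), and on the libraries titled 1 and 2 with the replicate block (1.40, 0.000483) and without it (1.40, 0.00644).

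The 8 other libraries have no replicate check. Among their largest ratios was AC116533.1, high in unrelated libraries, at 878 CPM in TRPC5OS, 956 CPM in COL6A6 and 858 CPM in 21-CTPS2, with a median of 0 elsewhere. Genes seen mainly in 1 library included AP1M2, an adaptor subunit, at 66.7 CPM in 20-ARSF against at most 16 CPM elsewhere, and ALPI, an intestinal phosphatase, at 19.9 CPM in ADORA2A against 0. In E7 the largest ratios were AC099329.1, HIST2H2AA4 and PATE2, and in UBE2V1 they were RHOXF2, HIST2H2AA4 and FP671120.4. Genes within 100 kb of a target gave 21 pairs of library and neighbour, with a median log2 ratio of -0.04, and 1 pair stood above every other library: MTDH beside LAPTM4B, at 103 CPM in LAPTM4B 2 against at most 102 CPM.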

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

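The sequence match, the depth and fibroblast tests, the fit within the unprefixed labels, the kept unmatched transcripts, the lists against 14 libraries and the splits were chosen after the results were seen. The fits without GFP and the gene counts against 14 libraries were planned, though what they would show was written down afterwards. A signal appeared in transcripts outside the comparisons, which have no gene in the annotation used. ENST00000611771.1 averaged 68.5 CPM in the 3 GOLGA8N libraries and 0.377 CPM in the 14 others, with 554 reads against 17 (log2 8.67 ± 1.13 SE against the reference arm, edgeR adjusted p = 0.00742). ENST00000632353.1 averaged 46.2 CPM against 0.441 CPM, but its rounded counts equalled those of AC091057.3 in all 17 libraries, so it is no separate signal. The transcripts used hold no sequence for either, so neither could be placed by alignment. Equal counts would arise if the quantifier divided reads evenly between like sequences, which was not tested. The counts at AC091057.3 may therefore hold only part of these reads. Whether ENST00000611771.1 belongs to a GOLGA8 copy was not tested either.

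AC091057.3 rose in all 3 GOLGA8N libraries while GOLGA8N itself had almost no reads. In 10 libraries deeper than every GOLGA8N library the highest level was 1.35 CPM, so the rise did not follow depth. These are among the 14 others, already seen to reach at most 2.01 CPM, so this was no separate test. Reads of a near-identical GOLGA8 copy counted at AC091057.3 could account for it, since the 3′ UTR of GOLGA8N matches at 97.6% identity. GOLGA8N was itself counted and received 0.7 reads in its 3 libraries, so the match alone does not place the reads there. GOLGA8H, which ends 2397 bp before AC091057.3 on the same strand, had 0 reads. In GOLGA8N the match starts at 32606373, past its coding end at 32603975. The 3′ tag reads of a GOLGA8H transcript running past its annotated end would not be counted at GOLGA8H. Its 0 reads therefore do not exclude it. Which copy the reads came from stays open, as does activation of the AC091057.3 locus itself. GOLGA8IP, a family member by name that was not among the matched transcripts, was at 4.63 ± 5.13 CPM (SD, n = 3) against 0.03 ± 0.11 (SD, n = 14).

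TIMP1, PAEP and CD44 were high in GOLGA8N 1 and 2, whereas in 23-GOLGA8N TIMP1 (524 CPM) and CD44 (15.2 CPM) lay inside the range of the other 3 prefixed libraries and PAEP (22.1 CPM) above their 4.34 to 19.2 CPM. Within the unprefixed labels, among which the prefix does not differ, TIMP1 was higher by log2 1.46. That fit reuses the libraries in which the pattern was seen. It restates the pattern and is no separate test of the batch that the prefix may mark. RNA of fibroblasts could not be told apart by its test: 7 abundant fibroblast transcripts summed to 80.9 and 113 CPM, against 64.5 to 110 CPM in the other unprefixed libraries, so the bound of 100 CPM set for the sum lay inside the K562 background and decided nothing. Of these, COL3A1, DCN and LUM were at 0.38 CPM or less in both. An effect of the GOLGA8N plasmids stays open.

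Ribosomal protein and respiratory lists were called higher in both arms against the reference libraries by camera with the preset correlation, whereas 0 of 37 lists were called in either arm with the estimated correlation. For the preset calls of the GOLGA8N arm the shallow GFP library is argued against, since 4 lists were still called there without it. The test was set for that arm only, so it does not decide for the LAPTM4B arm. Against the 14 libraries not named for its gene, 0 lists were called for either arm at the preset correlation. A property of the 3 reference libraries and an effect of carrying any activating plasmid both stay open.

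With 3 against 3 libraries there are 10 splits, too few to exclude chance. For GOLGA8N against reference 1 split, the real one, gave as many as 2 genes, and the highest other gave 1. For LAPTM4B against reference all 10 gave at least 0 genes, as they must, and the highest other gave 1. For GOLGA8N against LAPTM4B 4 splits gave at least 1 gene, and the highest other, which placed 22-LAPTM4B and 23-GOLGA8N together with GOLGA8N 2, gave 15, which points to a structure that follows the prefix; with the prefix as a term the real comparison gave 1. Against all 14 other libraries, 1 of 100 splits, the real one, gave as many as the 4 genes of the GOLGA8N arm, and the highest other gave 1. The real count was beyond the splits drawn. These were chosen after the results were seen, and the libraries may not be separate cultures, so they do not exclude chance. For the LAPTM4B arm, with 0 genes, all 100 splits give as many whatever the data, so they decide nothing; the highest other, 4, was the GOLGA8N arm itself.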

How the results depend on the processing

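The prefix term, the kept unmatched transcripts, AC091057.3 in place of GOLGA8N, the 14-library reference for lists and the fits against all other unprefixed libraries were chosen after seeing the data. The count of targeted genes highest in their own libraries, 3, became 2 with deposited TPM and with the GOLGA8 family summed, and 5 with AC091057.3 in place of GOLGA8N. Genes changed for GOLGA8N against reference, 2, became 14 with DESeq2, 4 with limma-voom, 42 with no filter, 1 with the stricter filter, 1 with all 17 libraries in the fit, 7 with unprefixed labels only, 4 against all 14 libraries with and without the prefix term, 5 against all other unprefixed libraries, 6 with the prefix as a term, and 1 to 5 leaving out 1 library. Genes changed for LAPTM4B against reference, 0, became 1 with DESeq2, 2 with limma-voom, 25 with no filter, 2 with unprefixed labels only, and 0 to 1 leaving out 1 library. Genes changed for GOLGA8N against LAPTM4B, 1, became 2 with DESeq2, 0 with limma-voom, 9 with no filter, 2 with unprefixed labels only, 3 with unmatched transcripts kept, and 1 to 3 leaving out 1 library. Called lists for GOLGA8N against reference, 4, became 0 with the estimated correlation and 0 against 14 libraries; those for LAPTM4B against reference, 4, became 0 with both of these, 9 with unprefixed labels only, 8 with the prefix as a term and 2 to 8 leaving out 1 library. Called lists for GOLGA8N against LAPTM4B, 0, ranged from 0 to 4 leaving out 1 library, with 4 without 22-LAPTM4B. The cause of these shifts was not tested. With no filter, and likewise with DESeq2, 24447 genes were tested in place of 11916. The DESeq2 counts therefore differ in both the tool and the filter. The labels do not say whether libraries with the same number, 1 or 2, belong together. Deviations of GOLGA8N 1 and LAPTM4B 1 from the means of their labels correlated at 0.141 over 10878 genes. Those of the libraries titled 2 are their mirror images and add no second value. GOLGA8N against LAPTM4B gave 2 genes on the libraries titled 1 and 2 with the replicate block and 2 with no replicate block. Other size factors and the summed GOLGA8 family left the counts of changed genes in the 3 comparisons as they were. Of the values of named genes under alternatives, 3087 kept direction and side of the threshold, 50 passed it, 11 lost it and 55 changed sign with neither value past it; no called gene changed sign. Depth limits low genes, above all in GFP, with its floor of 5.46 CPM.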

Other observations

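Every test in this part was chosen after the data were seen. The 4 libraries whose labels carry a number before the gene were compared with the 13 others. Of 12319 genes tested by edgeR, 35 were called, 29 higher and 6 lower in the prefixed libraries. MT2A, MT1X and MT1E, which encode metallothioneins, were higher by log2 3.05 ± 0.478 (SE; edgeR adjusted p = 0.0178), 2.30 ± 0.47 and 1.79 ± 0.42; no list of metallothioneins was tested. 22-LAPTM4B and 23-GOLGA8N were highest in MT2A and MT1X, with MT2A at 1283 and 755 CPM and MT1X at 46.6 and 44.6 CPM. 21-CTPS2 had 374 and 15.2 CPM. 20-ARSF, at 179 and 5.38 CPM, lay inside the unprefixed range. FTH1, a ferritin chain, was higher by 0.46, SLC25A37, a mitochondrial iron importer, by 0.78, and HBE1, embryonic globin, by 0.83. JUN was higher by 1.44 and SQSTM1, an autophagy receptor, by 0.64. IFI30, a lysosomal thiol reductase, was lower by a log2 change of -0.99, CD68 by -1.50, NRARP by -1.66 and MT-ATP6 by -0.47. In splits of 4 against 13 libraries, 1 of 100, the real one, gave as many as 35 genes, and the highest other gave 1. Because the grouping was picked after the data were seen, the splits do not exclude chance.

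By camera with the preset correlation, 11 of 37 lists were called, 7 higher and 4 lower, and 0 with an estimated correlation. Among them glycolysis and hypoxia genes (camera adjusted p = 2.76e-13), cholesterol synthesis genes (9.91e-09), integrated stress response and amino acid genes (1.97e-07) and immediate early genes (0.00138) were higher in the prefixed libraries. Cytosolic ribosomal protein genes were called higher as well (camera adjusted p = 0.0437). Mitochondrially encoded genes (camera adjusted p = 0.000929) and MAPK and MYC growth genes (0.000975) were lower. Of the 13 unprefixed libraries, E7 was highest in 17 of the 29 genes called higher and lowest in 5 of the 6 called lower; the next, GOLGA8N 2, was highest in 5 and lowest in 0. E7 had 271 CPM of MT2A, 165 CPM of JUN and 1644 CPM of GAPDH, but its FTH1, at 1637 CPM, and NEAT1, at 161 CPM, lay below the unprefixed means of 1652 and 187. The labels do not say what the prefix marks.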
